A study of Mus musculus with 13 samples.

How the data were processed

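RNA was extracted with Trizol and libraries were made with a TruSeq kit, per the labels' protocols, from 8 kidney samples and 5 mIMCD-3 cell samples. Samples were grouped by genotype and age (kidneys) or by the gapmer (cells) as the labels give them. The titles of the Pkd2 knockout samples carry "(WT)", while their genotype lists the Cre transgene and their description names a Pkd2 knockout, and they were grouped as knockouts. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.2a, Cufflinks 2.2.1, RSEM 1.2.22 and edgeR (no version) with build mm10 for the kidneys, and Trimmomatic 0.32, STAR 2.4.2a, SAMtools 1.0, DESeq2 1.12.3 and build GRCm38 (mm10) for the cells. The role and settings of each tool, the annotation and the strand setting of the counting are not given in the sources used here.

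The kidney values deposited by the authors are a signal per gene and library, read from the values as estimated CPM divided by a scaling factor per library. Low values of a library are whole multiples of the value of 1 read, which lay between 0.00820 and 0.0280, and 93.9% to 96.2% of the listed genes per library came out whole within 0.02 of a read. In Pkd1 control replicate 1, with the lowest share, a few values lay below that of 1 read and the step was taken from its most frequent low value, so its reads are the least certain. The recovered reads set the depth of each kidney library, and the deposited scaling was 1.02 times edgeR's TMM scaling of them in every library, a constant that leaves fold changes as they are. The cell values deposited by the authors are a signal too, read counts divided by a size factor per library, and all of them came out as whole multiples of a single step per library. The log2 fold changes deposited by the authors are control minus knockout in the kidney table and Hoxb3os gapmer minus control gapmer in the cell table, where they are moderated (slope 0.650 on the log2 ratio of group means). The p-values deposited by the authors are adjusted, per the file headers, and in the cell table the largest is 0.0500, so that table is a selection of genes. In the authors' deposited table, 2239 genes (1013 higher and 1226 lower in knockouts) had an adjusted p below 0.05 for Pkd1 and 2893 (1601 and 1292) for Pkd2, of which 1108 and 1724 were also called here.

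The design fixed before the data were examined assumed counts and named edgeR's quasi-likelihood test. Since the values are scaled, the test planned for values without counts was used instead, limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1). Kidney genes with a value of at least 1 in at least 2 libraries were tested in 1 fit of 4 groups over 8 libraries, with 4 residual degrees of freedom and a prior of 4.77. Contrasts were knockout minus control in each model, the difference of those effects (Pkd1 minus Pkd2), and older minus younger controls, which share libraries with the knockout contrasts. The 5 cell libraries had their own fit over the deposited genes, with 3 residual degrees of freedom and a prior of 36.2. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Pairwise correlations of the log2 values of the kidney libraries ran from 0.955 to 0.996.

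Gene lists (39 of them, for cell types of the kidney and of neighbouring tissue, pathways and gene families) were fixed before the data were examined, and those with at least 5 tested members were compared with all other genes by limma's camera with Benjamini-Hochberg adjustment over lists, with a preset correlation of 0.01 and, as an alternative, an estimated one. The T and B lymphocyte, adrenal gland and skeletal muscle lists had fewer and were not tested. In the cells, where the background is selected, camera was not run, and the direction of each list was set against that of the other deposited genes by two-sided Fisher's exact tests, a choice made after the data were seen. The rule for named genes, fixed beforehand, took Hoxb3os, Hoxb2, Hoxb3, Hoxb4, Hoxb5, Pkd1, Pkd2, Pkhd1 and Cdh16, the 8 called genes with the largest rise and the 8 with the largest fall (mean value at least 5, groups not overlapping, predicted genes, pseudogenes and small RNAs passed over), up to 4 members with the smallest adjusted p in each passing list and 2 of each other list, and the 5 largest shared rises and falls, with the same number each way for the difference between models. A gene named outside it is said to be chosen after its values were seen, or appears as a library check (Xist, the Y-linked genes, Alb, Ucp1, Adipoq and Hsd3b1). Some genes are not reported here.

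Alternatives were quantile scaling, no filter, a pseudocount of 0.1, DESeq2 1.42.0 on the recovered reads rounded to whole numbers, a fit on each model alone, a replicate block, mitochondrially encoded genes left out, a 2-fold minimum, and leaving out each library in turn, where a lone library is assumed to vary like the other groups. Added after the data were seen were edgeR 4.0.16's quasi-likelihood test on the recovered reads, covariates for sex (log2 of the summed Y-linked values) and for the share of small structural RNA, and crossed pairing. On recovered reads edgeR called 1583 genes for Pkd1, 2585 for Pkd2, 5 for their difference, 1920 between controls and 2016 of the deposited cell genes. Replicate numbers are not said to mark shared litters or days, and with 2 pairs per model they were not taken to pair samples. Coordinates and transcripts come from GENCODE M21 (GRCm38), the assembly of the authors' builds, and kidney gene identifiers were matched with it. The gapmer target was searched in its transcripts, not in introns or between genes.

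Tests were run on counts simulated from the real means and library sizes with 200 changed genes. For Pkd1 (14443 genes) limma recovered 31% of these at a log2 of 1 and 98% at 2, with 7 false calls. For Pkd2 (14432) it recovered 29% and 98%, with 14, and for cells (2016) 92% at 0.3 and 100% at 1, with 7. DESeq2 made 41, 43 and 4 false calls, so its kidney calls are less certain. Figures and enrichment tests used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.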

Results

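The transcripts of kidneys from a pair of mouse models of autosomal dominant polycystic kidney disease were profiled by RNA-seq, together with those of a mouse kidney cell line. In the Pkd1 model, a floxed Pkd1 gene meets the KSP/Cre transgene, a recombinase under the promoter of kidney-specific cadherin (Cdh16) that is active in tubule epithelium, and kidneys were taken at postnatal day 10. In the Pkd2 model, a floxed Pkd2 gene meets Pkhd1/Cre, which acts in collecting ducts, and kidneys were taken at postnatal day 20. Mice with the floxed gene and without Cre served as controls, with 2 libraries in each of the 4 kidney groups, all on the C57BL/6 strain. The mIMCD-3 line, derived from the inner medullary collecting duct, was transfected with 10 nM of a gapmer against the long noncoding RNA Hoxb3os (3 libraries) or of a control gapmer (2 libraries) and harvested after 48 hours. A gapmer is an antisense oligonucleotide whose DNA centre directs RNase H to cleave the bound RNA. The comparisons ask whether Hoxb3os and other genes are altered in the cystic kidneys, and which genes respond when Hoxb3os is targeted in cells, with the mTOR pathway as a named interest of the study.

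The kidney table listed 28183 genes, of which 14637 passed the filter on low values and were tested. The reads behind its values came to 94.4 and 55.5 M in Pkd1 control replicates 1 and 2, 53.9 and 34.1 M in the Pkd1 knockouts, 49.6 and 57.6 M in the Pkd2 controls and 40.2 and 30.7 M in the Pkd2 knockouts. The cell table held 2016 genes, all with an adjusted p below the threshold in the authors' deposited table, and the reads on those genes came to 8.77 and 14.4 M with the control gapmer and 10.3, 7.47 and 10.4 M with the Hoxb3os gapmer, part of each library and not its depth. Labels do not say whether replicates were separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Changes below are log2 fold changes on the log2(value + 1) scale ± SE, which understate the change of low genes, and each rests on 2 libraries per group unless stated. Adjusted p-values are Benjamini-Hochberg values. Numbers in parentheses after the counts of a list are its members higher and lower.

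Xist, transcribed from the inactive X chromosome of females, was at 0.221 and 416 in Pkd1 control replicates 1 and 2, 25.3 and 27.7 in the Pkd1 knockouts, 346 and 349.5 in the Pkd2 controls and 1.74 and 449 in the Pkd2 knockouts. The summed Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 155 and 10.4, 149 and 183, 0.104 and 0.0221, and 169 and 0.0462 in the same order, so sex was not balanced between groups. Mitochondrially encoded transcripts made up 27.4% and 38.7% of the values in the Pkd1 controls, 22% and 22.5% in the Pkd1 knockouts, 41.4% and 41.3% in the Pkd2 controls and 34.7% and 30.1% in the Pkd2 knockouts. Small structural RNAs such as the signal recognition particle RNA took 14% and 21.3%, 26.1% and 11.3%, 18% and 17.3%, and 20.7% and 5.40%, in that order. On the first principal component, with 51.8% of the variance, Pkd2 knockout replicates 1 and 2 lay at -0.765 and 33.4, farther apart than the libraries of any other group.

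The targeted genes come first. Pkd1, which encodes polycystin-1, was at 31.1 and 22.7 in the Pkd1 control libraries and 24.1 and 26 in the Pkd1 knockouts (-0.08 ± 0.19, limma Benjamini-Hochberg adjusted p = 0.82). Pkd2, which encodes polycystin-2, was at 69 and 61.2 in the Pkd2 controls and 50.7 and 53.3 in the Pkd2 knockouts (-0.32 ± 0.21, adjusted p = 0.33). A value per gene includes the exons that Cre leaves in place and the cells in which Cre is not active, so it checks neither label. In the other model, the log2 fold change of Pkd2 was -0.24 ± 0.21 in the Pkd1 kidneys and that of Pkd1 was 0.04 ± 0.19 in the Pkd2 kidneys. Pkhd1 and Cdh16, whose promoters drive the Cre transgenes, were at 0.45 ± 0.21 and 0.08 ± 0.23 in the Pkd1 kidneys and at 0.33 ± 0.21 and -0.16 ± 0.23 in the Pkd2 kidneys, none of which passed the test. Hoxb3os in the gapmer-treated cells was not analysed here, so its knockdown is unchecked for every gapmer result below.

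Hoxb3os was lower in every knockout library than in every control library of its model, and the change did not pass the test across all genes in either. Its values were 2.07 and 2.56 in the Pkd1 controls and 0.712 and 0.593 in the Pkd1 knockouts (2.32 ± 0.342 and 0.652 ± 0.0844, SD, n = 2 each). They were 2.60 and 1.99 in the Pkd2 controls and 1.71 and 0.370 in the Pkd2 knockouts (2.29 ± 0.434 and 1.04 ± 0.947). The log2 fold change was -1.0 ± 0.29 (limma Benjamini-Hochberg adjusted p = 0.062) in the Pkd1 model and -0.77 ± 0.29 (adjusted p = 0.10) in the Pkd2 model. The authors' deposited table gives a control-minus-knockout log2 value of 1.81 with an adjusted p of 0.00037 for Pkd1, and 1.16 with 0.044 for Pkd2. The effects in the 2 models were not found to differ (-0.24 ± 0.41, Pkd1 minus Pkd2, adjusted p = 0.99).

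The pseudocount of 1 shrinks changes of a gene as low as Hoxb3os. Its log2 fold changes in Pkd1 and Pkd2 were -1.68 and -1.36 with one of 0.1 (adjusted p = 0.089 and 0.12). With DESeq2 on recovered reads, less strict in simulation, they were -1.8 and -1.15 (0.013 and 0.15). Hoxb3os passed the test in the Pkd1 model with DESeq2 (adjusted p = 0.013), in a fit on the 4 Pkd1 libraries alone (0.014) and with a covariate for sex (0.021) or for small structural RNA (0.0082), while over all alternatives its adjusted p ran from 0.0082 to 0.22. In the Pkd2 model it passed without knockout replicate 1 (-1.26, adjusted p = 0.0043) and with the sex covariate (0.027), and not without knockout replicate 2 (-0.27, 0.51), the ends of its range being 0.0043 and 0.51.

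Hoxb3os lies on the minus strand of chromosome 11 between 96343072 and 96354691 (GRCm38). It overlaps Hoxb3, on the plus strand from 96323326 to 96347930, and Hoxb2, on the plus strand from 96350525 to 96354012. Whether reads were counted by strand is not given in the sources used here, so reads of Hoxb3os and of these antisense partners may not have been told apart, and its values are uncertain for that reason. The gapmer sequence ATTACTGCTTCTTCCA pairs with TGGAAGAAGCAGTAAT, which occurs without mismatch in 1 annotated transcript, Hoxb3os-202. That transcript has 4 exons and 1945 nt, and the site starts at its nucleotide 1710, in exon 2 (96348289 to 96348388), at 96348296 to 96348311 of chromosome 11, within a noncoding exon outside the annotated exons of Hoxb3 and Hoxb2. Hoxb2, Hoxb3, Hoxb4 and Hoxb5 had log2 fold changes of 0.12 ± 0.21, -0.35 ± 0.25, -0.40 ± 0.17 and -0.29 ± 0.24 in the Pkd1 model and 0.45 ± 0.21, 0.01 ± 0.25, -0.39 ± 0.17 and -0.30 ± 0.24 in the Pkd2 model, none of which passed the test. Over the HoxB cluster as a list, the Pkd1 kidneys had 1 higher, 1 lower and 9 not called of 11 (1 and 2 adjusted over the list alone), with Hoxb9 (0.75 ± 0.17) and Hoxb5os (-0.93 ± 0.23) as the called members, and the Pkd2 kidneys had 1 higher, 0 lower and 10 not called of 11 (0 and 0 adjusted over the list alone), with Hoxb9 at 0.57 ± 0.17. The list did not pass camera in either model (adjusted p = 0.20 and 0.84).

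**Figure D1:**
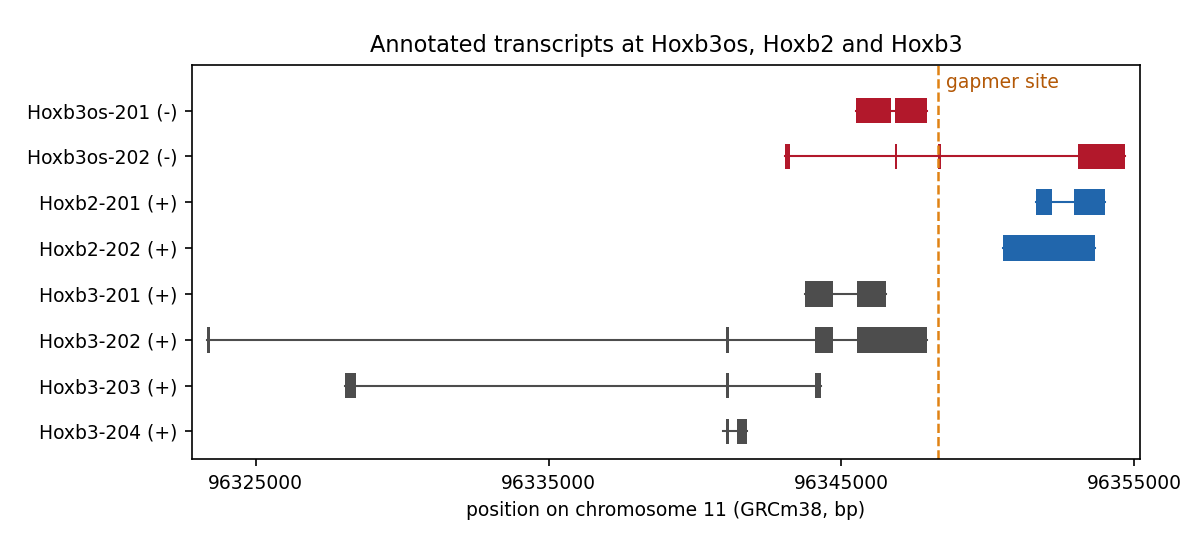
Map of chromosome 11 around Hoxb3os (GRCm38, position in bp on the horizontal axis), with the annotated exons of Hoxb3 and Hoxb2 on the plus strand, those of Hoxb3os on the minus strand and the gapmer site. The site at 96348296 to 96348311 falls in exon 2 of Hoxb3os-202, between the exons of Hoxb3 and Hoxb2.

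**Figure D2:**
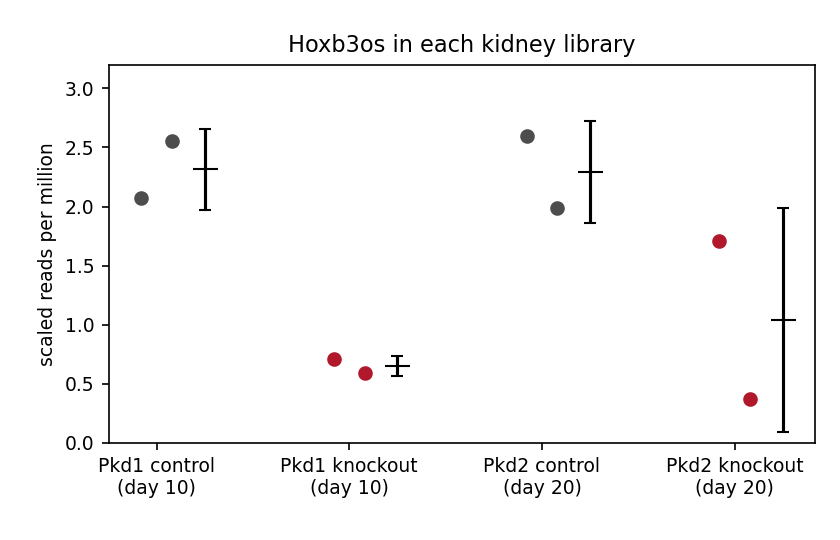
Hoxb3os in each kidney library (points; scaled CPM), with the mean and SD of each group of 2 libraries. Control libraries lie between 1.99 and 2.60, and knockout libraries between 0.370 and 1.71.

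In the Pkd1 knockout kidneys, the largest rises were those of Actg2 (4.36 ± 0.22), the gamma actin of smooth muscle, Col12a1 (4.13 ± 0.24), a collagen that coats fibrils, Il18r1 (3.84 ± 0.23), a receptor chain for interleukin 18, Lcn2 (3.77 ± 0.31), a lipocalin released by injured tubules, and Fos (3.73 ± 0.37), an immediate early transcription factor. S100a14 (3.27 ± 0.40) and Mal2 (3.14 ± 0.34) and the EGF receptor ligand Btc (3.12 ± 0.31) followed. The largest falls were those of Egf (-3.66 ± 0.27), a growth factor of the thick ascending limb and distal tubule, Klk1 (-3.28 ± 0.46), the kallikrein of the connecting tubule, Cdkn1c (-2.78 ± 0.20), a cyclin-dependent kinase inhibitor, and Miox (-2.73 ± 0.44), which breaks down inositol in the proximal tubule. The carriers Slc13a3 (-2.63 ± 0.37), Slc5a2 (-2.52 ± 0.29) and Slc16a4 (-2.4 ± 0.18) and the glutathione transferase Gsta2 (-2.6 ± 0.51) fell as well. In total, 1550 of 14637 genes passed limma's test at a Benjamini-Hochberg adjusted p below 0.05, 748 higher and 802 lower, and 904 of them changed at least 2-fold. Both knockout libraries lay beyond both controls in 58.3% of genes, against 33.3% by chance.

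Inflammatory groups rose together. Among macrophage markers 17 rose, 0 fell and 3 of 20 were not called (19 and 0 adjusted over the list alone). Mrc1 (2.02 ± 0.19) and C1qa (1.59 ± 0.16) were among those called. Among chemokines and cytokines 7 rose, 0 fell and 6 of 13 were not called (12 and 0 adjusted over the list alone). Cxcl16 (1.21 ± 0.16) and Il34 (1.17 ± 0.19) were called members. In the complement list 4 rose, 1 fell and 9 of 14 were not called (5 and 1 adjusted over the list alone). The receptors C5ar1 (1.46 ± 0.18) and C3ar1 (1.16 ± 0.16) and the component C3 (1.32 ± 0.33) rose. Macrophage, chemokine and complement lists passed camera upward (adjusted p = 1.7e-15, 1.0e-07 and 0.024). None of these calls held with an estimated correlation (adjusted p = 0.21, 0.28 and 0.28 with it). Injury and matrix genes moved the same way. Of the tubule injury genes 11 rose, 0 fell and 9 of 20 were not called (11 and 2 adjusted over the list alone). Lcn2 (3.77 ± 0.31) and Krt18 (2.55 ± 0.23) passed the test. Of the matrix genes 14 rose, 0 fell and 16 of 30 were not called (19 and 2 adjusted over the list alone). Postn (2.1 ± 0.20) and Acta2 (2.08 ± 0.21) are examples. Of the YAP and TAZ targets, which respond to cell stretch and density, 8 rose, 0 fell and 8 of 16 were not called (8 and 0 adjusted over the list alone). Ctgf (2.67 ± 0.20) and Ankrd1 (2.85 ± 0.30) were among them. Tubule injury, matrix and YAP and TAZ lists passed camera upward (adjusted p = 3.0e-09, 1.9e-08 and 9.6e-06). They were lost with an estimated correlation, at adjusted p = 0.28, 0.34 and 0.28.

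Among immediate early genes 7 rose, 0 fell and 11 of 18 were not called (14 and 0 adjusted over the list alone). Egr2 (3.07 ± 0.28) and Fos (3.73 ± 0.37) were among those called. Among p53 targets 5 rose, 1 fell and 14 of 20 were not called (7 and 1 adjusted over the list alone). Pmaip1 (1.91 ± 0.22) and Btg2 (1.15 ± 0.17) were called members. Among targets of ATF4, which answers amino acid shortage, 5 rose, 1 fell and 15 of 21 were not called (7 and 1 adjusted over the list alone). The amino acid genes Asns (2.53 ± 0.21), Slc7a5 (1.55 ± 0.21) and Psat1 (1.33 ± 0.28) rose. Immediate early, p53 and ATF4 lists passed camera upward (adjusted p = 1.9e-08, 0.00051 and 0.00033). The adjusted p with an estimated correlation was 0.28, 0.28 and 0.21, so no call held. Among markers of collecting duct principal cells 5 rose, 0 fell and 10 of 15 were not called (7 and 0 adjusted over the list alone). The vasopressin receptor Avpr2 (1.84 ± 0.20), the sodium channel subunits Scnn1a (1.89 ± 0.18) and Scnn1g (1.01 ± 0.23) and Tmem229a (0.98 ± 0.20) were called. Among mitotic genes 2 rose, 0 fell and 18 of 20 were not called (2 and 0 adjusted over the list alone). The called genes were Ccnb1 (0.75 ± 0.17) and Tpx2 (0.75 ± 0.19). In glycolysis 1 rose, 0 fell and 17 of 18 were not called (1 and 0 adjusted over the list alone). Pfkp (1.17 ± 0.26) passed and Slc16a3 (2.18 ± 0.67) and Hk2 (1.68 ± 0.53) did not. Among ribosomal proteins 1 rose, 0 fell and 31 of 32 were not called (0 and 0 adjusted over the list alone). Rps6 (0.76 ± 0.20) passed. Principal cell, mitosis, glycolysis and ribosomal lists passed camera upward (adjusted p = 0.00081, 0.00033, 0.0033 and 0.0018). None of these calls held with an estimated correlation (adjusted p = 0.50, 0.56, 0.67 and 0.67 with it).

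Markers of the other nephron segments fell. Of the proximal tubule genes 0 rose, 17 fell and 12 of 29 were not called (0 and 25 adjusted over the list alone). The glucose and phosphate carriers Slc5a2 (-2.52 ± 0.29) and Slc34a1 (-2.32 ± 0.28) and the endocytic receptor Cubn (-1.55 ± 0.21) fell. Of the thick ascending limb genes 0 rose, 8 fell and 7 of 15 were not called (0 and 12 adjusted over the list alone). Egf (-3.66 ± 0.27) and Tmem72 (-1.68 ± 0.24) passed the test. Of the distal convoluted tubule genes 1 rose, 5 fell and 4 of 10 were not called (1 and 6 adjusted over the list alone). Slc12a3 (-1.74 ± 0.24) and Wnk4 (-1.23 ± 0.22) are examples. Of the intercalated cell genes 1 rose, 9 fell and 6 of 16 were not called (2 and 13 adjusted over the list alone). Rhbg (-2.06 ± 0.18) and Slc26a4 (-1.78 ± 0.17) were among them. The proximal tubule, thick limb, distal tubule and intercalated lists passed camera downward (adjusted p = 1.8e-14, 3.1e-07, 0.0042 and 9.2e-07). They were lost with an estimated correlation, at adjusted p = 0.28, 0.28, 0.45 and 0.21. Of the podocyte genes 1 rose, 6 fell and 5 of 12 were not called (1 and 7 adjusted over the list alone). Nphs1 (-1.57 ± 0.19) and Ptpro (-1.23 ± 0.15) were among those called. Of the endothelial genes 0 rose, 4 fell and 11 of 15 were not called (0 and 5 adjusted over the list alone). Plvap (-1.47 ± 0.32) and Tek (-1.02 ± 0.23) were called members. In the HoxA, HoxC and HoxD clusters 0 rose, 2 fell and 16 of 18 were not called (0 and 7 adjusted over the list alone). Hoxc5 (-0.78 ± 0.18) and Hoxa9 (-0.78 ± 0.19) passed the test. Podocyte, endothelial and Hox lists passed camera downward (adjusted p = 0.00012, 0.00075 and 0.0047). The adjusted p with an estimated correlation was 0.21, 0.56 and 0.62, so no call held.

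For oxidative phosphorylation 0 rose, 1 fell and 33 of 34 were not called (0 and 0 adjusted over the list alone), with Uqcrc1 (-0.72 ± 0.19) as the called member and a median of -0.55. For fatty acid oxidation 0 rose, 1 fell and 21 of 22 were not called (0 and 1 adjusted over the list alone), with Hadh (-1.1 ± 0.23) called. For mitochondrially encoded genes 0 rose, 0 fell and 15 of 15 were not called (0 and 0 adjusted over the list alone), with a median of -1.19, mt-Nd5 at -1.78 ± 0.52 and mitochondrial shares of 27.4% and 38.7% in controls against 22% and 22.5% in knockouts. The oxidative phosphorylation, mitochondrially encoded and fatty acid oxidation lists passed camera downward (adjusted p = 8.6e-06, 0.00081 and 0.0047). None of these calls held with an estimated correlation (adjusted p = 0.64, 0.64 and 0.67 with it).

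The mTOR pathway list did not pass in the Pkd1 kidneys. Of its genes 4 rose, 1 fell and 35 of 40 were not called (4 and 1 adjusted over the list alone). The kinase subunit Pik3cb (0.93 ± 0.21) and the translation repressor Eif4ebp1 (0.88 ± 0.21) rose (list, camera adjusted p = 0.84). Other lists that did not pass are given with members higher, lower and not called, those higher and lower adjusted over the list alone, and camera's adjusted p. They were polycystic kidney genes (0, 1 and 14, 0 and 1, 0.97), DNA replication (0, 0 and 20, 0 and 0, 0.13), interferon response (2, 1 and 22, 3 and 1, 0.28), Wnt targets (1, 1 and 9, 1 and 2, 0.66) and FoxO targets (1, 1 and 18, 1 and 1, 0.83), then sterol synthesis (0, 1 and 27, 0 and 0, 0.84), cilium (0, 1 and 24, 0 and 0, 0.24), nephron progenitor (0, 1 and 11, 0 and 1, 0.37), erythroid (0, 0 and 7, 0 and 0, 0.80), adipose tissue (1, 0 and 10, 1 and 1, 0.28) and sex-linked (0, 0 and 5, 0 and 0, 0.33). Among their members, Nkd2 (1.21 ± 0.17), Oas2 (1.14 ± 0.26) and Lep (1.33 ± 0.18) rose and Umod (-1.24 ± 0.26), Rsad2 (-1.63 ± 0.17), Notum (-1.4 ± 0.34), Dnah5 (-0.87 ± 0.21) and Sall1 (-0.85 ± 0.18) fell. The polycystic kidney list had a median of 0.02 and a mean of -0.04 with a downward test, and the sterol list a median of -0.04 and a mean of 0.04 with a downward test. All 23 passing lists kept their direction under quantile scaling, and so did those that could be run with mitochondrially encoded genes left out.

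The count of called genes rested on every library, at 325 without control replicate 1, 346 without control replicate 2, 510 without knockout replicate 1 and 788 without knockout replicate 2, and 44, 36, 33 and 30 of the 85 called genes named for this comparison lost their call in turn. Of the called 67.1, 52.3, 57.8 and 46.8% were then higher, against 48.3% with all libraries. The count was 790 with no filter, 2491 with a sex covariate and 2683 with one for small structural RNA, both chosen after the data were seen.

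In the Pkd2 knockout kidneys, Lcn2 (6.01 ± 0.31) and Havcr1 (5.77 ± 0.42), the kidney injury molecule of damaged proximal tubules, had the largest rises, followed by Il18r1 (4.64 ± 0.23), Col12a1 (4.64 ± 0.24) and Lgi2 (4.26 ± 0.23), Dio2 (4.12 ± 0.39), which activates thyroid hormone, S100a14 (3.91 ± 0.40) and the metalloproteinase inhibitor Timp1 (3.65 ± 0.27). The largest falls were those of Alb (-3.72 ± 0.59), albumin, Kcnt1 (-3.69 ± 0.38), Cacna2d2 (-3.67 ± 0.26), a calcium channel subunit, and Ucp1 (-3.63 ± 0.69), the uncoupling protein of brown fat. Egf (-3.51 ± 0.27), Ppp1r1b (-3.26 ± 0.31), Wfdc15b (-3.04 ± 0.46) and Klk1 (-3.0 ± 0.46) fell next. Albumin stood at 18.2 and 11.7 in the controls and 0.392 and 0 in the knockouts, and Ucp1 at 15.2 and 24.4 against 1.71 and 0. In total, 2587 of 14637 genes passed limma's test, 1397 higher and 1190 lower, and 1345 of them changed at least 2-fold. Both knockout libraries lay beyond both controls in 62.7% of genes, against 33.3% by chance.

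Among macrophage markers 19 rose, 0 fell and 1 of 20 were not called (20 and 0 adjusted over the list alone). Mrc1 (2.68 ± 0.19) and Cd14 (2.67 ± 0.19) are examples. Among chemokines and cytokines 12 rose, 0 fell and 1 of 13 were not called (13 and 0 adjusted over the list alone). The neutrophil attractants Cxcl1 (2.68 ± 0.30) and Cxcl2 (1.54 ± 0.22) rose, as did Lif (2.35 ± 0.33). Among complement genes 7 rose, 0 fell and 7 of 14 were not called (9 and 0 adjusted over the list alone). C3 (3.14 ± 0.33) and Cfi (1.96 ± 0.23) were among them. Among interferon response genes 5 rose, 1 fell and 19 of 25 were not called (6 and 1 adjusted over the list alone). Oas2 (2.31 ± 0.26) and Cxcl10 (1.7 ± 0.37) were among those called. These immune lists passed camera upward (adjusted p = 6.4e-20, 5.7e-10, 3.6e-06 and 0.0017). They were lost with an estimated correlation, at adjusted p = 0.12, 0.32, 0.12 and 0.56. Of the tubule injury genes 18 rose, 0 fell and 2 of 20 were not called (19 and 0 adjusted over the list alone), including Krt18 (3.06 ± 0.23) and Anxa1 (2.14 ± 0.18) beside Lcn2 and Havcr1. Of the matrix genes 16 rose, 0 fell and 14 of 30 were not called (21 and 0 adjusted over the list alone). Timp1 (3.65 ± 0.27) and Acta2 (2.4 ± 0.21) were called members. Of the YAP and TAZ targets 7 rose, 0 fell and 9 of 16 were not called (8 and 0 adjusted over the list alone). Ankrd1 (3.64 ± 0.30) and Cyr61 (2.1 ± 0.31) passed the test. Injury, matrix and YAP and TAZ lists passed camera upward (adjusted p = 9.2e-16, 5.9e-13 and 9.1e-05). The adjusted p with an estimated correlation was 0.32, 0.32 and 0.34, so no call held.

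Cell cycle genes rose as a group. Of the mitotic genes 19 rose, 0 fell and 1 of 20 were not called (20 and 0 adjusted over the list alone). Cenpe (1.65 ± 0.23) and Mki67 (1.59 ± 0.27) are examples. Of the replication genes 6 rose, 0 fell and 14 of 20 were not called (9 and 0 adjusted over the list alone). Uhrf1 (1.39 ± 0.21) and Cdc6 (1.06 ± 0.25) were among them. Of the p53 targets 7 rose, 1 fell and 12 of 20 were not called (8 and 1 adjusted over the list alone). Pmaip1 (1.8 ± 0.22) and Eda2r (1.41 ± 0.28) were among those called. Of the immediate early genes 8 rose, 1 fell and 9 of 18 were not called (8 and 1 adjusted over the list alone). Egr2 (3.06 ± 0.28) and Atf3 (2.37 ± 0.36) were called members. Of the principal cell genes 6 rose, 0 fell and 9 of 15 were not called (7 and 0 adjusted over the list alone). The transcription factor Elf5 (1.29 ± 0.22) and Scnn1b (1.13 ± 0.26) and Hsd11b2 (0.99 ± 0.18) rose. Mitosis, replication, p53, immediate early and principal cell lists passed camera upward (adjusted p = 3.4e-12, 5.2e-05, 0.00088, 0.00088 and 0.011). None of these calls held with an estimated correlation (adjusted p = 0.32, 0.53, 0.34, 0.53 and 0.56 with it).

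Proximal tubule, thick limb, distal tubule and intercalated cell markers fell here too. For the thick ascending limb 0 rose, 12 fell and 3 of 15 were not called (0 and 14 adjusted over the list alone). Egf (-3.51 ± 0.27) and Ppp1r1a (-2.57 ± 0.34) passed the test. For the distal convoluted tubule 1 rose, 6 fell and 3 of 10 were not called (1 and 7 adjusted over the list alone). Pvalb (-2.54 ± 0.25) and Calb1 (-2.39 ± 0.33) are examples. For the proximal tubule 1 rose, 14 fell and 14 of 29 were not called (1 and 23 adjusted over the list alone). Slc34a3 (-1.91 ± 0.33) and Gatm (-1.85 ± 0.30) were among them. For intercalated cells 1 rose, 9 fell and 6 of 16 were not called (2 and 11 adjusted over the list alone). Rhbg (-1.37 ± 0.18) and Atp6v1c2 (-1.31 ± 0.19) were among those called. Proximal tubule, thick limb, distal tubule and intercalated lists passed camera downward (adjusted p = 3.4e-09, 1.6e-09, 0.00017 and 0.00014). They were lost with an estimated correlation, at adjusted p = 0.47, 0.32, 0.34 and 0.32. For endothelium 0 rose, 1 fell and 14 of 15 were not called (0 and 0 adjusted over the list alone), the called gene being Emcn (-0.79 ± 0.22). For the HoxA, HoxC and HoxD clusters 0 rose, 4 fell and 14 of 18 were not called (0 and 4 adjusted over the list alone). Hoxc5 (-0.94 ± 0.18) and Hoxc6 (-0.85 ± 0.24) were called members. For adipose tissue genes 0 rose, 1 fell and 10 of 11 were not called (0 and 7 adjusted over the list alone), the called one being Ucp1, beside Cfd (-2.01 ± 0.66), Plin1 (-1.62 ± 0.53) and Fabp4 (-1.14 ± 0.37). Adipoq, a fat cell hormone, stood at 3.14 and 5.71 in the controls and 2.05 and 0.116 in the knockouts. Endothelial, Hox and adipose lists passed camera downward (adjusted p = 0.013, 0.0031 and 0.00057). The adjusted p with an estimated correlation was 0.59, 0.56 and 0.53, so no call held. Hsd3b1, a steroid-making enzyme of the adrenal gland, stood at 1.51 and 63.5 in Pkd2 control replicates 1 and 2 and at 0.0561 and 0 in the knockouts.

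Of the oxidative phosphorylation genes 0 rose, 26 fell and 8 of 34 were not called (0 and 34 adjusted over the list alone). Cyc1 (-1.47 ± 0.25) and Sdhb (-1.36 ± 0.22) passed the test. Of the fatty acid oxidation genes 0 rose, 7 fell and 15 of 22 were not called (0 and 8 adjusted over the list alone). The regulators Ppargc1a (-1.28 ± 0.23) and Ppara (-1.25 ± 0.26) and the enzyme Hadh (-1.08 ± 0.23) fell. Of the FoxO targets 1 rose, 4 fell and 15 of 20 were not called (2 and 7 adjusted over the list alone). Klf15 (-1.64 ± 0.29) and the antioxidant enzymes Sod2 (-1.14 ± 0.23) and Cat (-0.95 ± 0.21) fell. Of the sterol genes 0 rose, 2 fell and 26 of 28 were not called (0 and 1 adjusted over the list alone), with Lss (-0.70 ± 0.15) among those called. Of the mitochondrially encoded genes 0 rose, 0 fell and 15 of 15 were not called (0 and 0 adjusted over the list alone), with a median of -1.42 and mitochondrial shares of 41.4% and 41.3% in controls against 34.7% and 30.1% in knockouts. Oxidative phosphorylation, mitochondrially encoded, fatty acid, FoxO and sterol lists passed camera downward (adjusted p = 2.0e-14, 0.00057, 0.00040, 0.037 and 0.043). None of these calls held with an estimated correlation (adjusted p = 0.44, 0.56, 0.57, 0.56 and 0.70 with it). The sterol list no longer passed under quantile scaling (adjusted p = 0.064), and the erythroid list then passed (0.048). All 24 passing lists kept their direction under that scaling, as did those that could be run without mitochondrially encoded genes.

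The mTOR pathway list did not pass in the Pkd2 kidneys either. Of its genes 1 rose, 3 fell and 36 of 40 were not called (0 and 0 adjusted over the list alone). The insulin receptor substrate Irs1 (-0.68 ± 0.16) and the mTORC1 component Akt1s1 (-1.22 ± 0.30) fell (list, camera adjusted p = 0.48). In the same form as for Pkd1, the other lists were polycystic kidney genes (1, 1 and 13, 0 and 1, 0.48), podocyte (1, 3 and 8, 1 and 3, 0.23), nephron progenitor (2, 3 and 7, 3 and 3, 0.79), erythroid (0, 0 and 7, 0 and 0, 0.17) and sex-linked (0, 0 and 5, 0 and 0, 0.34), then glycolysis (1, 1 and 16, 0 and 0, 0.48), ATF4 targets (2, 3 and 16, 2 and 4, 0.94), Wnt targets (3, 0 and 8, 3 and 1, 0.31), cilium (1, 1 and 23, 1 and 1, 0.55) and ribosomal proteins (0, 0 and 32, 0 and 0, 0.48). In these, Bicc1 (0.71 ± 0.21), Wnt4 (1.09 ± 0.17), Wnt9b (1.0 ± 0.20), Nkd2 (2.05 ± 0.17) and Slc16a3 (2.41 ± 0.67) rose and Umod (-1.13 ± 0.26), Podxl (-1.0 ± 0.17), Nphs1 (-0.90 ± 0.19), Slc3a2 (-0.82 ± 0.19) and Dnah11 (-1.33 ± 0.20) fell. The glycolysis list had a median of -0.19 and a mean of 0.04 with a downward test, and the ATF4 list a median of 0.05 and a mean of 0.02 with a downward test.

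The count of called genes in the Pkd2 model was 772 without control replicate 1, 621 without control replicate 2, 4253 without knockout replicate 1 and 1024 without knockout replicate 2, and 31, 41, 3 and 28 of the 90 called genes named for this comparison lost their call in turn. The share of called genes that were higher was 65, 75.2, 46.7 and 64.9% in that order and 49.4% with a covariate for sex, against 54% with all libraries and no covariate, so the balance of directions was not stable. Lep and Syndig1 in Pkd1 and Dnah11, Cxcl2 and Syndig1 in Pkd2 dropped below the filter without some libraries. A fit on the 4 Pkd2 libraries alone called 1379 genes.

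The Pkd1 and Pkd2 effects differed for 1 gene, Serpina10, which encodes the protein Z-dependent protease inhibitor. It stood at 6.70 and 8.24 in Pkd1 controls and 6.49 and 6.90 in Pkd1 knockouts, and at 3.69 and 2.96 in Pkd2 controls and 34.1 and 27.3 in Pkd2 knockouts. Its Pkd1-minus-Pkd2 difference was -3.0 ± 0.27 (limma Benjamini-Hochberg adjusted p = 0.025), with -0.13 ± 0.19 in Pkd1 and 2.87 ± 0.19 in Pkd2. Havcr1 (-4.81 ± 0.60, adjusted p = 0.063) and Asns (2.11 ± 0.30, 0.066) did not pass. At an unadjusted p below 0.05 limma gave 1207 genes against 732 by chance. On recovered reads edgeR called 5 and DESeq2, less strict in simulation, 179. The models differ in gene, Cre line and age at once, so the difference cannot be assigned to any.

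As groups, inflammatory and cell cycle lists had the larger rise in the Pkd2 kidneys, and respiratory chain and distal tubule lists the larger fall. Serpina10 is in none of the lists, so no member was called over all genes by limma, and the lists are given with the median Pkd1-minus-Pkd2 difference, the members higher and lower adjusted over the list alone, camera's adjusted p, and the adjusted p with an estimated correlation. Passing downward were macrophage (-0.78, 0 and 8, 1.3e-12, 0.13), mitosis (-0.70, 0 and 0, 2.1e-11, 0.51), DNA replication (-0.34, 0 and 0, 0.00023, 0.61), tubule injury (-0.51, 0 and 4, 1.2e-06, 0.61), complement (-0.65, 0 and 7, 6.9e-06, 0.12), chemokine (-0.59, 0 and 1, 0.0024, 0.61), matrix (-0.28, 0 and 4, 0.0031, 0.63), interferon (-0.37, 0 and 0, 0.0013, 0.61), proximal tubule (-0.27, 0 and 0, 0.016, 0.74), podocyte (-0.43, 0 and 2, 8.4e-05, 0.16) and erythroid (-0.70, 0 and 0, 0.034, 0.62). Passing upward were adipose (1.92, 3 and 0, 2.2e-08, 0.52), oxidative phosphorylation (0.64, 0 and 0, 3.2e-10, 0.61), ATF4 (0.43, 1 and 0, 1.3e-06, 0.12), glycolysis (0.58, 0 and 0, 1.4e-05, 0.61), distal convoluted tubule (0.39, 2 and 0, 0.0029, 0.61), thick ascending limb (0.19, 0 and 0, 0.017, 0.63), FoxO (0.41, 0 and 0, 0.0057, 0.61), ribosomal protein (0.32, 0 and 0, 0.0065, 0.74), sterol (0.23, 0 and 0, 0.017, 0.74) and immediate early (0.26, 2 and 0, 0.018, 0.63). None passed with an estimated correlation. Under quantile scaling the thick ascending limb (adjusted p = 0.29) and ribosomal protein (0.42) lists no longer did, while the intercalated cell list then passed (0.027, and 0.041 with mitochondrially encoded genes left out), with the direction of every passing list kept. The members with the smallest p in the macrophage list were Ccr2 (-2.06 ± 0.44), Cd14 (-1.23 ± 0.27) and Ms4a7 (-1.55 ± 0.34), those of the tubule injury list Havcr1 (-4.81 ± 0.60), Clu (-2.66 ± 0.47) and Vcam1 (-2.25 ± 0.43), and those of the adipose list Lep (1.47 ± 0.26), Ucp1 (3.83 ± 0.97) and Adipoq (2.37 ± 0.75), none of which passed over all genes. The proximal tubule list passed downward, its fall being the larger in the Pkd1 kidneys.

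The other lists did not pass for the difference between models. By camera's adjusted p they were principal cell (0.39), intercalated cell (0.056), endothelium (0.38), nephron progenitor (0.62), sex-linked (0.91), HoxB (0.23), other Hox clusters (0.62), polycystic kidney (0.42), mTOR (0.13), mitochondrially encoded (0.62), fatty acid oxidation (0.080), p53 (0.93), YAP and TAZ (0.78), Wnt (0.15) and cilium (0.62). Adjusted over the list alone, 1 principal cell gene, Scnn1a (1.7 ± 0.26), and 1 YAP and TAZ target, Ctgf (1.8 ± 0.28), were higher and 2 nephron progenitor genes, Wnt9b (-1.49 ± 0.28) and Wnt4 (-0.96 ± 0.23), lower, with 0 in the other lists. Median and test differed in sign for the principal cell list (median -0.12, mean 0.14, upward), the HoxA, HoxC and HoxD list (-0.06, 0.03, upward) and the YAP and TAZ list (-0.07, 0.04, upward), and mean and test for the sex-linked list (-0.71, 0.02, downward).

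Serpina10 kept its call without either Pkd2 knockout replicate and lost it without each other library. The count for the difference was 0 without any of Pkd1 control replicates 1 and 2, Pkd1 knockout replicate 1 or Pkd2 control replicates 1 and 2 (limma, with 841, 1024, 1214, 712 and 857 genes at an unadjusted p below 0.05), 2 without Pkd1 knockout replicate 2, 26 without Pkd2 knockout replicate 1 and 3 without Pkd2 knockout replicate 2. It was 8 under quantile scaling, 5 with a pseudocount of 0.1, 6 with the sex covariate, 27 with that for small structural RNA and 0 by limma with no filter (2126 at an unadjusted p below 0.05).

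Most genes called in both models moved the same way in both. With the Pkd1 value before the Pkd2 value, the largest shared rises were those of Col12a1 (4.13 and 4.64), Il18r1 (3.84 and 4.64), Lcn2 (3.77 and 6.01), S100a14 (3.27 and 3.91) and Egr2 (3.07 and 3.06). The largest shared falls were those of Egf (-3.66 and -3.51), Klk1 (-3.28 and -3.0), Miox (-2.73 and -2.35), Ppp1r1a (-2.24 and -2.57) and Dcxr (-2.09 and -2.07). Genes higher in both numbered 521, against 71.4 if the calls were independent (odds ratio 34.1, one-sided Fisher's exact test, log10 p = -385). Those lower in both numbered 445, against 65.2 (odds ratio 21.9, log10 p = -294). Genes are not independent replicates, so these p-values describe the overlap of the lists only, and the models share no control library. Across genes the log2 fold changes correlated at 0.74, and among genes called in both the slope of Pkd2 on Pkd1 was 0.99. A further 5 genes, named after their values were seen, were lower in Pkd1 and higher in Pkd2, namely Olfml3 (-0.83 and 0.70), Mdk (-0.71 and 0.81), Lrrtm1 (-1.53 and 0.82), Ros1 (-0.81 and 2.0) and Syndig1 (-0.91 and 0.81), and 0 of the genes called in both by limma went the other way. The 966 shared genes became 1757 with a covariate for sex and 512 with a 2-fold minimum in both.

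**Figure D3:**
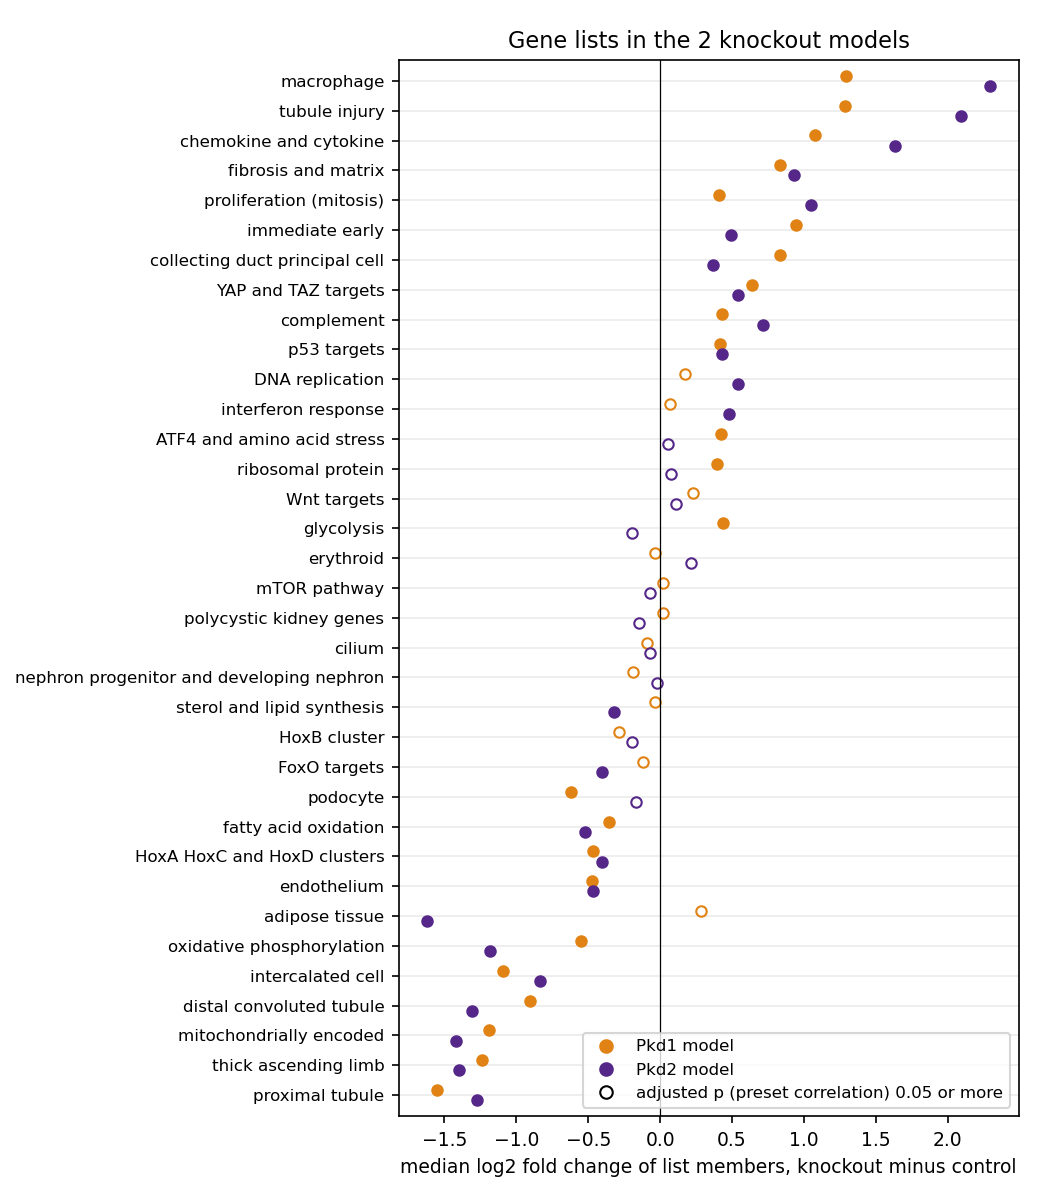
Median log2 fold change of gene lists fixed beforehand, in the Pkd1 and Pkd2 knockout comparisons. Filled points passed camera (Benjamini-Hochberg adjusted p below 0.05, preset correlation) and open points did not. Macrophage, injury and matrix lists lie above 0 and proximal tubule, thick ascending limb, distal convoluted tubule and intercalated cell lists below 0 in both, and none passed with an estimated correlation.

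The controls of the models were compared as background, since the Pkd2 controls were taken at postnatal day 20 and the Pkd1 controls at day 10 and also differ in the floxed gene. The largest rises were those of Egf (4.89 ± 0.27), Serpina1f (4.46 ± 0.24), Dnase1 (4.35 ± 0.22), Kcnt1 (4.0 ± 0.38), Gc (3.69 ± 0.59), the vitamin D-binding protein, Hsd11b1 (3.69 ± 0.35), which regenerates active glucocorticoid and Ces1d (3.65 ± 0.36). The largest falls were those of H19 (-3.83 ± 0.27), an imprinted noncoding RNA, Afp (-3.66 ± 0.23), alpha-fetoprotein, Clec18a (-3.26 ± 0.27), Lgi2 (-3.09 ± 0.23), Igf2 (-3.05 ± 0.18), a fetal growth factor and Cdkn1c (-2.92 ± 0.20). Hoxb3os was at -0.01 ± 0.29 and Hoxb3 fell (-0.94 ± 0.25, limma Benjamini-Hochberg adjusted p = 0.038). In total 1801 genes were called, 738 higher and 1063 lower in the older, 970 of them at least 2-fold, and groups did not overlap in 62.3% of genes, against 33.3% by chance.

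Growth programmes were lower in the older controls. Of the mitotic genes 0 rose and 20 fell of 20 (0 and 20 adjusted over the list alone). Tpx2 (-1.94 ± 0.19) and Nusap1 (-1.88 ± 0.21) are examples. Of the replication genes 0 rose, 14 fell and 6 of 20 were not called (0 and 19 adjusted over the list alone). Uhrf1 (-2.14 ± 0.21) and Mcm6 (-1.7 ± 0.18) were among them. Of the Wnt targets 0 rose, 7 fell and 4 of 11 were not called (0 and 7 adjusted over the list alone). Apcdd1 (-2.09 ± 0.32) and Nkd2 (-2.01 ± 0.17) were among those called. Of the matrix genes 0 rose, 10 fell and 20 of 30 were not called (0 and 12 adjusted over the list alone). Thbs2 (-2.7 ± 0.16) and Acta2 (-2.51 ± 0.21) were called members. Of the podocyte genes 0 rose, 9 fell and 3 of 12 were not called (0 and 9 adjusted over the list alone). Wt1 (-1.46 ± 0.19) and Tcf21 (-1.17 ± 0.23) passed the test. Mitosis, replication, Wnt, matrix and podocyte lists passed camera downward (adjusted p = 4.8e-20, 7.3e-13, 4.0e-05, 7.6e-08 and 1.1e-06). They were lost with an estimated correlation, at adjusted p = 0.55, 0.57, 0.57, 0.61 and 0.33. In the other Hox clusters 0 rose, 3 fell and 15 of 18 were not called (0 and 3 adjusted over the list alone). Hoxd11 (-1.32 ± 0.18) and Hoxa11 (-1.12 ± 0.20) are examples. Of the ribosomal proteins 0 rose, 1 fell and 31 of 32 were not called (0 and 1 adjusted over the list alone), with Rplp0 (-0.97 ± 0.21). The Hox and ribosomal lists passed camera downward (adjusted p = 0.0042 and 0.039). The adjusted p with an estimated correlation was 0.67 and 0.76, so no call held.

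Of the proximal tubule genes 6 rose, 0 fell and 23 of 29 were not called (11 and 0 adjusted over the list alone). Cyp2e1 (2.66 ± 0.37) and Slc27a2 (1.68 ± 0.35) were among them. Of the thick limb genes 6 rose, 0 fell and 9 of 15 were not called (7 and 0 adjusted over the list alone), with Umod (2.19 ± 0.26), Ptger3 (1.8 ± 0.28) and Kcnj1 (1.03 ± 0.20) beside Egf. Of the distal tubule genes 3 rose, 0 fell and 7 of 10 were not called (3 and 0 adjusted over the list alone). Pvalb (1.76 ± 0.25) and Calb1 (1.28 ± 0.33) were among those called. Of the interferon response genes 8 rose, 0 fell and 17 of 25 were not called (16 and 0 adjusted over the list alone). Ifit3 (1.68 ± 0.19) and Irf7 (1.67 ± 0.24) were called members. Of the FoxO targets 3 rose, 0 fell and 17 of 20 were not called (6 and 0 adjusted over the list alone). Klf15 (1.31 ± 0.29) and Cat (1.29 ± 0.21) passed the test. Proximal tubule, thick limb, distal tubule, interferon and FoxO lists passed camera upward (adjusted p = 9.0e-07, 2.0e-05, 0.0053, 2.2e-10 and 0.0032). None of these calls held with an estimated correlation (adjusted p = 0.65, 0.61, 0.65, 0.57 and 0.65 with it). For oxidative phosphorylation 7 rose, 0 fell and 27 of 34 were not called (7 and 0 adjusted over the list alone). Uqcrfs1 (1.1 ± 0.24) and Cycs (1.01 ± 0.25) are examples. Mitochondrially encoded genes had 0 higher, 0 lower and 15 not called of 15 (0 and 0 adjusted over the list alone), fatty acid oxidation 2 higher, 0 lower and 20 not called of 22 (2 and 0 adjusted over the list alone), glycolysis 1 higher, 0 lower and 17 not called of 18 (1 and 0 adjusted over the list alone) and adipose tissue 0 higher, 0 lower and 11 not called of 11 (0 and 0 adjusted over the list alone), with Ppara (1.35 ± 0.26), Hadhb (0.96 ± 0.21) and Pfkp (1.16 ± 0.26) among those called and Cfd (2.09 ± 0.66) and Ucp1 (2.16 ± 0.69) not called. Oxidative phosphorylation, mitochondrially encoded, fatty acid, glycolysis and adipose lists passed camera upward (adjusted p = 6.0e-09, 0.0069, 0.0091, 0.039 and 0.0029). They were lost with an estimated correlation, at adjusted p = 0.65, 0.72, 0.72, 0.72 and 0.67. The mitochondrial share was 27.4% and 38.7% in the younger and 41.4% and 41.3% in the older controls, and Ucp1 stood at 6.23 and 1.86 against 15.2 and 24.4.

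Lists that did not pass, in the form used for Pkd1, were HoxB (0, 1 and 10, 0 and 2, 0.15), mTOR pathway (1, 1 and 38, 1 and 1, 0.48), polycystic kidney genes (1, 0 and 14, 1 and 0, 0.67), tubule injury (2, 2 and 16, 2 and 2, 0.34), macrophage (0, 0 and 20, 0 and 0, 0.91), chemokines (2, 0 and 11, 2 and 0, 0.17) and complement (1, 1 and 12, 1 and 1, 0.45), then principal cell (3, 0 and 12, 3 and 0, 0.11), intercalated cell (1, 0 and 15, 6 and 0, 0.061), endothelium (0, 1 and 14, 0 and 1, 0.96), nephron progenitor (0, 3 and 9, 0 and 4, 0.12), erythroid (0, 0 and 7, 0 and 0, 0.24) and sex-linked (0, 0 and 5, 0 and 0, 0.17), and ATF4 (3, 1 and 17, 5 and 1, 0.11), sterol synthesis (1, 0 and 27, 0 and 0, 0.15), p53 (2, 1 and 17, 2 and 1, 0.96), immediate early (2, 1 and 15, 3 and 1, 0.15), YAP and TAZ (3, 2 and 11, 3 and 5, 0.96) and cilium (1, 0 and 24, 1 and 0, 0.82). Of their members, Deptor (0.83 ± 0.15) rose and Wnt4 (-1.72 ± 0.17), Wnt9b (-2.01 ± 0.20) and Prr5l (-1.03 ± 0.19) fell. Signs differed within the macrophage (median 0.01, mean -0.02, upward), endothelial (median 0.14, mean -0.01, upward), p53 (median 0.04, mean -0.02, upward) and YAP and TAZ (median -0.22, mean 0.01, downward) lists. Passing lists kept their direction under quantile scaling, where the mitochondrially encoded (0.13), fatty acid (0.065) and glycolysis (0.24) lists no longer passed by camera's adjusted p. The count of called genes was 403 and 780 without Pkd1 control replicates 1 and 2 and 428 and 497 without Pkd2 control replicates 1 and 2, and 17, 12, 14 and 14 of the 47 called genes named here lost their call, in that order. It was 1077 with the sex covariate, of which 52.4% were higher against 41% without it, and 2954 with that for small structural RNA.

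In mIMCD-3 cells, the Hoxb3os gapmer was followed by small shifts of many genes and large shifts of few. Among the deposited genes the largest rises were those of Ly6g (2.73 ± 0.29), Sulf2 (2.18 ± 0.28), BC025446 (1.54 ± 0.26), Ak1 (1.41 ± 0.15), Lncenc1 (1.36 ± 0.14), Ulbp1 (1.26 ± 0.23), a ligand of an immune receptor, Gc (1.22 ± 0.28) and Ebf1 (1.21 ± 0.20). The largest falls were those of the phosphatases Ptprg (-2.08 ± 0.09) and Ppm1l (-1.63 ± 0.07), Gulp1 (-1.48 ± 0.14), Mfi2 (-1.47 ± 0.28), Ikbke (-1.31 ± 0.07), a kinase of innate immune signalling, Fam92b (-1.24 ± 0.26), the adhesion molecule Ncam1 (-1.22 ± 0.10) and Smad9 (-1.21 ± 0.29). Pkhd1, whose product is fibrocystin, fell (-0.34 ± 0.05, limma Benjamini-Hochberg adjusted p = 1.4e-07). The table holds only genes that passed the authors' own test, so counts here are within the deposited genes only. Of 2016, 2015 passed limma's test, 895 higher and 1120 lower, and 43 changed at least 2-fold, against 4 by the moderated values of the authors' deposited table. The 3 Hoxb3os gapmer libraries lay on one side of both controls in 2014 genes, a count that the selection of the table raises.

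Amino acid, sterol and ribosomal genes rose in the cells and fatty acid oxidation genes fell. Among ATF4 targets 15 rose and 0 fell of 15 deposited, with Chac1 (0.66 ± 0.10), Asns (0.47 ± 0.05) and Psat1 (0.36 ± 0.04). Among sterol and lipid synthesis genes 16 rose and 1 fell of 18 deposited, with the sterol synthesis enzymes Mvd (0.37 ± 0.06) and Msmo1 (0.33 ± 0.05). Among ribosomal proteins 19 rose and 0 fell of 19 deposited, with Rplp1 (0.25 ± 0.05) and Rps2 (0.24 ± 0.05). Among p53 targets 8 rose and 1 fell of 9 deposited, with Plk2 (0.66 ± 0.05), Aen (0.47 ± 0.07) and Ccng1 (0.39 ± 0.04). Among YAP and TAZ targets 9 rose and 1 fell of 10 deposited, with Ctgf (0.79 ± 0.07), Amotl2 (0.47 ± 0.05) and Cyr61 (0.34 ± 0.05). Among fatty acid oxidation genes 0 rose and 10 fell of 10 deposited, with Ppargc1a (-0.59 ± 0.09), Acot1 (-0.53 ± 0.10) and Cpt1a (-0.32 ± 0.04). The counts were the same adjusted over the list alone. Against other deposited genes, these lists differed in direction by two-sided Fisher's exact tests, which allow for no correlation between genes. Benjamini-Hochberg adjusted p was 2.9e-05, 4.0e-05, 2.2e-06, 0.026, 0.016 and 0.0091 in that order, over 12 lists with at least 5 deposited members. Under quantile scaling the members with a positive change went from 17 to 16 for the sterol list and from 19 to 18 for ribosomal proteins and did not differ in the other tested lists, while the median of all deposited genes moved from -0.14 to -0.11.

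Of the mTOR pathway genes 3 rose and 5 fell of 8 deposited, with Irs2 (0.37 ± 0.07), an insulin receptor substrate, up and Rragd (-0.54 ± 0.10), a Rag GTPase that recruits mTORC1, down. Its direction was not found to differ from that of the other deposited genes (two-sided Fisher's exact test, adjusted p = 0.81). Likewise, for tubule injury 5 rose and 4 fell of 9 deposited (Anxa3 (0.38 ± 0.04) and Sprr1a (-0.49 ± 0.06)), for polycystic kidney genes 2 rose and 3 fell of 5 deposited (Pkhd1 and Dnajb11 (0.18 ± 0.05)), for glycolysis 1 rose and 6 fell of 7 deposited (Hk2 (0.33 ± 0.06) and Gpi1 (-0.20 ± 0.04)), for immediate early genes 5 rose and 2 fell of 7 deposited (Dusp6 (0.73 ± 0.07) and Egr1 (-0.47 ± 0.07)) and for FoxO targets 1 rose and 5 fell of 6 deposited (Irs2 and Txnip (-0.34 ± 0.04)), with adjusted p of 0.63, 1, 0.24, 0.34 and 0.34 in that order. The other lists had fewer than 5 deposited members and were not tested. Of the 15 members of the HoxB list, Hoxb3os included, 1 was among the cell genes analysed, Skap1 (-0.69 ± 0.18).

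Without each Hoxb3os gapmer library in turn, 1976 to 2001 of the deposited genes passed and 0 of the 51 named lost their call. A test on these libraries had selected the genes, so this does not measure stability.

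**Figure D4:**
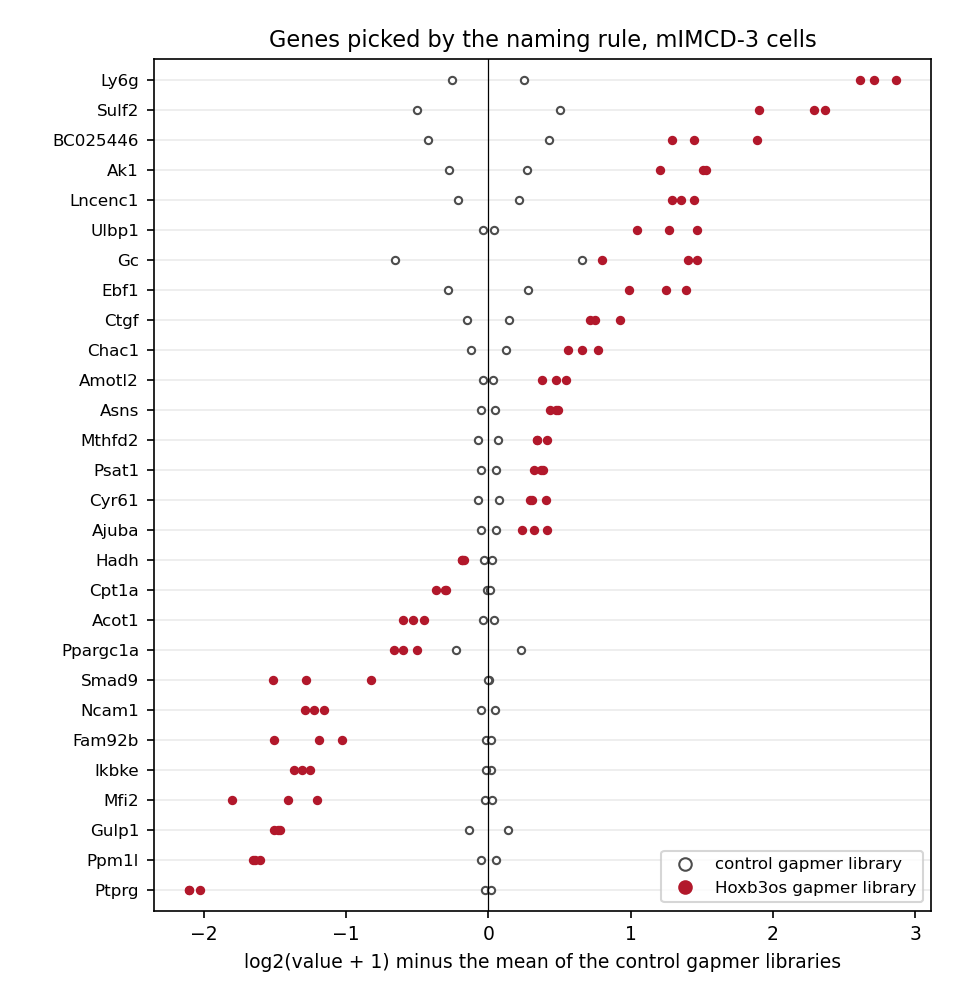
Log2 value of each library relative to the mean of the control gapmer libraries, for genes taken from those the naming rule picked, in mIMCD-3 cells (points are libraries, 2 control and 3 Hoxb3os gapmer). Ptprg and Ppm1l lie below and Ly6g and Sulf2 above their controls in all 3 gapmer libraries.

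Genes that shifted in the cells were then followed in the kidneys, where 1889 of them were tested. Several moved the same way in cells, Pkd1 and Pkd2 kidneys, among them the matrix and contact genes Ctgf (0.79, 2.67 and 0.87) and Fxyd5 (0.69, 0.97 and 1.21), which rose, and Ptprd (-1.01, -1.15 and -1.28), Ppp1r1b (-0.75, -1.29 and -3.26), Esrrg (-0.65, -0.88 and -0.83), Plekha6 (-0.75, -0.69 and -0.70), Tcea3 (-0.90, -1.01 and -1.04) and Aatk (-0.90, -1.0 and -1.04), which fell (log2 fold changes in that order; chosen after their values were seen, from those with the largest smallest change). Of 224 such genes called in the Pkd1 kidneys, 152 moved in the direction seen in the cells and 72 in the opposite one (odds ratio 6.39, 95% interval 3.27 to 13, two-sided Fisher's exact test across genes, p = 1.5e-09). By the same Fisher's exact test, in the Pkd2 kidneys the numbers were 216 and 167 of 383 (odds ratio 2.21, 1.40 to 3.54, p = 0.00039), and between older and younger controls 125 and 134 of 259 (odds ratio 0.726, 0.415 to 1.26, p = 0.24). Genes that rose in the cells were higher 74 and lower 16 times in the Pkd1 and 103 and 42 in the Pkd2 kidneys, and those that fell were higher 56 and lower 78 times and 125 and 113, so in Pkd2 the surplus in the same direction came from genes that rose. Of 144 deposited genes called the same way in both models, 49 were higher and 45 lower in all 3 comparisons, and 50 went the opposite way in the cells. Over all 1889 genes the fold changes in cells correlated with those in the kidneys at 0.155 (Pkd1) and 0.0984 (Pkd2), and genes are not independent replicates. With changes of at least 2-fold on both sides, 1 of 4 genes in each model had the same direction.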

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

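Listed here are results where the planned test of the Pkd1-minus-Pkd2 difference passed. Serpina10 differed by -3.0 (Pkd1 minus Pkd2, log2), with a rise in the Pkd2 knockouts and none that passed in the Pkd1 knockouts. The macrophage (1.3e-12), mitosis (2.1e-11), DNA replication (0.00023), tubule injury (1.2e-06), complement (6.9e-06), chemokine (0.0024), matrix (0.0031), interferon (0.0013), podocyte (8.4e-05), proximal tubule (0.016) and erythroid (0.034) lists had a lower Pkd1-minus-Pkd2 difference than other genes, with camera's adjusted p in parentheses. The adipose (2.2e-08), oxidative phosphorylation (3.2e-10), ATF4 (1.3e-06), glycolysis (1.4e-05), distal convoluted tubule (0.0029), thick ascending limb (0.017), FoxO (0.0057), ribosomal protein (0.0065), sterol (0.017) and immediate early (0.018) lists had a higher one. With an estimated correlation none of these lists passed. Gene, Cre line and age differ between the models together, sex was unbalanced, and fat and adrenal transcripts varied by library. No explanation was tested.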

How the results depend on the processing

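The covariates, edgeR and the crossed pairing were chosen after the data were seen. Leaving out 1 library gave 325 to 788 called genes for Pkd1 (main 1550), 621 to 4253 for Pkd2 (2587), 0 to 26 for their difference (1), 403 to 780 between controls (1801) and 1758 to 2001 in cells (2015), where the design then has fewer samples. With no filter, Pkd1 fell to 790 and the difference to 0 (limma, 2126 at an unadjusted p below 0.05). The 2-fold minimum, by its construction, left 904, 1345, 970 and 43 genes for Pkd1, Pkd2, controls and cells, 512 in both models, and 1 and 1 cell genes with the same direction in Pkd1 and Pkd2. The sex covariate gave 2491 for Pkd1, 6 for the difference, 1077 between controls and 1757 in both models. That for small structural RNA gave 2683, 27 and 2954 for Pkd1, the difference and controls. The difference was also 8 under quantile scaling, 5 with the smaller pseudocount, 5 with edgeR and 179 with DESeq2, and a fit on the Pkd2 libraries alone called 1379. The cause of these shifts was not tested. With an estimated correlation 0, 0, 0 and 0 lists passed camera, against 23, 24, 21 and 17. No gene called in the kidneys changed sign under any alternative, and 2 of the cell genes did under quantile scaling, Rps12 (0.12 to -0.0038) and Rpl5 (0.11 to -0.0090), named after their values were seen. Of the 4716 values of named genes under alternatives, 4088 kept direction and side of the threshold, 551 were no longer past it and 55 were newly past it.

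With the replicate number as a block, 1044 (Pkd1), 1812 (Pkd2), 0 (their difference by limma, with 954 at an unadjusted p below 0.05), 1226 (controls) and 1967 (cells) genes were called, and 625 in both models. Then 90 and 143 cell genes had the same direction in Pkd1 and Pkd2, 23, 24, 20 and 16 lists passed camera, and Hoxb3os had adjusted p of 0.042 and 0.071. Deviations of same-numbered libraries correlated at -0.378 in the Pkd1 and -0.0490 in the Pkd2 model, and with 2 pairs the numbers were not taken to pair samples. Pairing the Pkd1 libraries crosswise called 1479 genes. At this depth and with 2 libraries per group, simulated changes near 2-fold in the kidneys were recovered in part.

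Named genes that were not called changed sign under some alternatives. They were Cdh16 in Pkd1 (-0.081 to 0.23 without 1 library, -0.019 with quantile scaling), Cdh16 in Pkd2 (-0.38 to 0.067 without 1 library, 0.080 with quantile scaling), Hoxb2 in Pkd1 (-0.014 with sex covariate), Hoxb3 in Pkd2 (-0.33 to 0.35 without 1 library, -0.0024 with quantile scaling, -0.31 with sex covariate), Hoxb3os in the difference (-0.73 to 0.26 without 1 library), Hoxb3os in controls (-0.15 to 0.12 without 1 library, 0.085 with quantile scaling, 0.016 with DESeq2, 0.011 with edgeR, 0.49 with sex covariate), Hoxb5 in Pkd1 (-0.59 to 0.010 without 1 library), Pkd1 in Pkd1 (-0.30 to 0.13 without 1 library), Pkd1 in Pkd2 (-0.12 to 0.20 without 1 library, -0.096 with small RNA covariate) and Pkd2 in Pkd1 (-0.54 to 0.063 without 1 library). The cause was not tested.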

Other observations

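Tests of RNA or reads from the Pkd2 control libraries and from the Pkd1 knockout libraries in control replicate 2, those of near sites in bins of transcript length, with 2 or fewer mismatches and with shuffles pooled, and the simulated shares were chosen after the result was seen, and the other tests here were set before it, though every pattern was noticed in the same data. Genes named in the next paragraph were chosen after their values were seen.

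Genes far apart between younger and older controls moved either way in the knockouts. Lgi2, which was lower in the older controls (-3.09 ± 0.23), rose in both models (1.78 ± 0.23 in Pkd1 and 4.26 ± 0.23 in Pkd2). Igf2 (-1.14 ± 0.18 and -0.73 ± 0.18) and Cdkn1c (-2.78 ± 0.20 and -1.52 ± 0.20), imprinted genes that were likewise higher in the younger controls, fell instead, while H19 (-0.43 ± 0.27 and -0.49 ± 0.27) passed in neither.

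The Pkd1 change had a covariance of -0.0449 with the older-minus-younger control difference across genes. Chance values of the shared Pkd1 control libraries would give a positive one, 0.0275 to 0.0337 in 100 simulations, which argues against them as the source. A whole-profile return to younger kidneys stays open as part of it. Of 738 genes higher in older controls, 67.9% had a negative Pkd1 change (121 called lower, 41 higher). Of 1063 higher in younger, 53.1% had a positive one (88 called higher but 111 lower). Shared controls alone would give 28.2 to 39.1% and 33.8 to 42.5% (simulated). In Pkd2 the shares were 84.6% and 83.9%, beside 60.9 to 70.7% and 57.4 to 66.8%, with a covariance of -0.186 beside -0.0340 to -0.0280. Age, gene and Cre line are confounded, sex and fat or adrenal transcripts uneven, and all stay open as sources, untested.

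Genes that fell after the Hoxb3os gapmer span more of the genome than genes that rose, with medians of 41.7 and 15.7 kb (ratio 2.67, permutation p = 1e-05, the smallest 100000 permutations can give), whereas the ratio was 0.930 and 0.764 among genes called in the Pkd1 and Pkd2 kidneys. A bias with transcript length is argued against as the whole source, since within bins of transcript length the median ratio was still 1.84 (1.48 to 5.96). Sites with 3 or fewer mismatches to the gapmer target were in 7.71% of genes that fell and 4.39% of those that rose (odds ratio 1.82, 1.22 to 2.76), and the ratio was 1.47 (0.992 to 2.17) with transcript length in bins. Longer transcripts of the genes that fell, which hold more near matches of any sequence, could give part of it, since 100 shuffled targets pooled had 1.44 and 24 of them a ratio as large (0.731 to 15.3), which few sites could inflate, at a median of 2.50% of genes against 6.24%. Of the 15 genes with 2 or fewer mismatches 13 fell, 86.7% against 55.6% of all searched (two-sided Fisher's exact test, p = 0.017) and 64.9% for shuffled targets, so cleavage at near-complementary sites in mature transcripts stays open beside transcript length. Sequence-dependent cleavage in introns, with more sites in longer genes, remains a candidate explanation because introns were not searched here and the 187 genes with the strongest falls spanned 1.42 times more than the other genes that fell (permutation p = 0.017), as does a response to loss of Hoxb3os, for which no second gapmer was analysed here.

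Pkd1 control replicate 2 and both Pkd1 knockout libraries held transcripts of both sexes, with Xist at 5.64% and 6.18% of the highest library in the knockouts and Y-linked genes at 5.68% in the control. RNA or reads from the Pkd2 control libraries are argued against for the knockouts, since 5 genes far higher in the Pkd2 controls reached a median of 0.0876 of the level the Xist share would bring. RNA or reads from the Pkd1 knockout libraries in control replicate 2, RNA or reads shared between the Pkd1 control and knockout libraries, and pooled kidneys of both sexes within one genotype cannot be told apart, and no biological explanation was tested, as the labels give no sex. At the Y-linked share of 6.26%, 4 genes (Col12a1, Il18r1, Actg2 and Fos, named after their values were seen) of 4819 lay below the level it would bring to control replicate 2, by the upper end of their 95% counting interval, but at the lowest share of a Y-linked gene, 4.45%, 2 (Actg2 and Fos) did, too few to decide. Below 3% of the other genotype's mean lay 4 genes in control replicate 2, 2 in control replicate 1 and 0 and 0 of 4845 in the knockouts, under the 5 needed, beside 1 and 2 in the Pkd2 knockouts and 7 and 6 in the Pkd2 controls.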
